A study of Homo sapiens with 14 samples.

How the data were processed

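Affymetrix arrays with 22277 probe sets were analysed for 14 samples of SKI-DLCL, 12 of cultured cells and 2 of tumours grown in scid mice. The number of animals behind each tumour array is not given in the sources used here. Per the labels, RNA was extracted with RNeasy and labelled as biotinylated cRNA with the ENZO kit. The deposited values are linear signal intensities, 1 per probe set and array, and the algorithm that summarised them is not given in the sources used here. On every array the mean after trimming 2% from each end was 150 to 150.1, so the values had been scaled to a common trimmed mean, and they were used as deposited. The lowest mean signal among genes tested was 14.7. No 2 arrays were identical (highest share of equal values, 1.48%). GAPDH 3 prime to 5 prime ratios were 0.965 to 1.018 on the cultured-cell arrays and ACTB ratios 1.283 to 1.418.

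Probe sets were annotated from the platform table with symbols updated through the Entrez identifier (19052 probe sets). Those listed with 1 gene (19064) were kept, and 62 control probe sets, 1043 with several genes and 2108 with none were left out. For each of 11963 genes the probe set with the highest mean was used. The choices in this and the next 2 paragraphs were made before the data were examined, unless another time is given. Of 24 genes fixed in advance, 2 had no single-gene probe set in the annotation used and are not analysed here, and EEF1A2, CDA, FOS and FLT1 lay under the filter.

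Values were analysed as log2 of the signal plus 16 for the upper 60% of genes by mean, 7178 in all. The 12 cultured-cell arrays were fitted together in limma 3.58.1 (R 4.3.3) with empirical Bayes and a trend, and the 3 treatments were compared with untreated cells and with each other. Benjamini-Hochberg adjusted p values under 0.05 over all genes tested were counted as changes. A further test asked whether any of the 3 treatments changed a gene. The doses of each drug differ between the single treatments and the combination, so synergy was not tested. Counts of genes whose 3 treated values all lay above or below the 3 untreated values are given beside the 10% expected by chance.

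Gene lists were 25 for the study's processes and 5 for other cell types, with 937 genes, of which 815 were on the array. They cover the BCL2 family and caspases, mitochondrial permeability, oxidative phosphorylation, mitochondrial translation, NRF2, the integrated stress response, endoplasmic reticulum stress, heat shock, immediate early genes, NF-kB targets, interferon response, DNA replication, G2/M, histones, DNA repair, cytarabine and nucleotide metabolism, translation factors, ribosomal proteins, ribosome biogenesis, sterol synthesis, hypoxia, proteasome, B cell identity and plasma cells. The other cell types are T and NK, myeloid, fibroblast, endothelial and erythroid. The result of 1 list is not reported here. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. In culture, 23 tested list genes belong to more than 1 list.

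The genes named for each comparison with untreated cells are the 10 largest increases and 10 largest decreases among genes past the threshold whose treated values all lay beyond the untreated ones. For direct comparisons 5 and 5 were taken. From each list up to 4 changed genes with the largest change were eligible, together with the fixed genes, and the tumour text draws on the 10 highest and 10 lowest genes and the list genes. The tumour arrays (1 each) were compared without a test, and list medians were placed among 10000 random lists of matched expression.

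The fit was tested on simulated data made from these arrays. In each comparison 67 genes were changed by 0.25 on the log2 scale, another 67 by 0.5 and 66 by 1. Of these it recovered 28.4%, 73.1% and 100% for Aplidin, 35.8%, 73.1% and 97% for AraC, and 25.4%, 76.1% and 100% for the combination. False calls made up 3.3%, 4.9% and 3.2% of the calls. A DNA replication list shifted by 0.2 was found in each comparison (adjusted p = 4.76e-34, 4.48e-33 and 8.12e-36) with 0 other lists called. Genes were simulated as independent of each other, so this result says nothing about false list calls that come from correlated genes. Shared responses were compared with 100 simulations of groups without an effect, and counts with 100 random splits or with all 10 splits of 6 arrays (seed 11).

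Alternatives set in advance were a pseudocount of 1 or 64, no filter, the upper 40% of genes, quantile normalization, scaling to one median, all probe sets, only the 2 groups compared in the fit, empirical Bayes without a trend, the replicate number as a block, and each array left out in turn. For single genes all of these were run except all probe sets and the fit of only 2 groups. Chosen after seeing the data were leaving 1 replicate number out of all 4 groups, leaving out single arrays for the lists and the shared response, and limiting the tumour genes to those within 2-fold of untreated culture.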

Results

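Gene expression was measured on 14 Affymetrix arrays in SKI-DLCL, an established human line of diffuse large cell lymphoma, grown in culture or as tumours in scid mice. Cultured cells were kept for 24 h without drug, with Aplidin at 3 nM, with AraC at 20 nM, or with Aplidin at 1.5 nM together with AraC at 5 nM, and each of these 4 groups holds 3 arrays from biological triplicates. Aplidin (plitidepsin) is a cyclic depsipeptide that binds the translation elongation factor eEF1A. AraC (cytosine arabinoside) is a nucleoside analogue that is phosphorylated in the cell and then blocks DNA synthesis. The other 2 arrays hold tumour RNA from untreated animals and from animals given 1 mg/kg Aplidin with 50 mg/kg AraC and sampled on day 8, and are called the untreated and the treated tumour here. Values are linear signal intensities with a trimmed mean of 150 to 150.1 on every array. The median signal was 20.8 to 25.4 on the cultured-cell arrays and 37 and 38.5 on the tumour arrays. Replicate arrays of 1 group correlated across genes with r from 0.989 to 0.994, genes not being independent replicates, and the 3 arrays per group limit the precision (median SE of a log2 fold change, 0.094). At least 1 of the 3 treatments changed 3053 of the 7178 genes tested.

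The first comparison addresses what Aplidin alone does to these cells. Aplidin lowered the lists of endoplasmic reticulum stress, sterol synthesis and integrated stress response genes, and its largest increases included CXCR4, JUN and BACH2. HSPA5, the main luminal chaperone, fell from a signal of 3576 ± 124 to 1639 ± 71.9 (mean ± SD, n = 3 each; log2 fold change -1.12 ± 0.05 SE, adjusted p = 1.06e-09). DHCR7, the last enzyme of cholesterol synthesis, fell from 521 ± 11.1 to 196 ± 6.8 (-1.34 ± 0.05, adjusted p = 9.16e-11). CXCR4, a chemokine receptor of B cells, rose from 233 ± 48 to 803 ± 90.5 (1.73 ± 0.12, adjusted p = 3.34e-08). BACH2, a transcription factor of germinal centre B cells, rose from 140 ± 14.1 to 444 ± 11.5 (1.57 ± 0.13, adjusted p = 1.42e-07). In all, 2667 genes changed, 1356 up and 1311 down, of which 16 rose and 27 fell by at least 1 on the log2 scale. With each array scaled to one median, which moved the median of all genes by -0.101, the split was 543 up and 1735 down. The treated and untreated values did not overlap for 3394 genes (47.3%), where chance gives 10%.

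Beside CXCR4 and BACH2, the largest increases included JUN, the AP-1 subunit, from 11.8 ± 4.1 to 68.4 ± 5.8 (1.61 ± 0.14, a size that depends on the added 16, above the untreated signal). They also included CLEC2D, a ligand of a natural killer cell receptor, at 1.47 ± 0.08, the cannabinoid receptor gene CNR1 at 1.46 ± 0.07, and the leukocyte tetraspanin CD53, from 452 to 1224 (1.41 ± 0.10). RUBCNL, a regulator of autophagy, rose by 1.54, CXCR5, the receptor that guides B cells to follicles, by 1.33, ITPR1, a calcium channel of the endoplasmic reticulum, by 1.27, and the synaptotagmin SYT17 by 1.20. HSP90B1, the second large luminal chaperone, fell most on the log2 scale of signal plus 16, from 271 ± 27.5 to 66.2 ± 16.8 (-1.82 ± 0.15), although its 1 other probe set was not called. The secreted glycoprotein SPP1 (-1.68), the integrin subunit ITGB7 (587 to 183, -1.60 ± 0.07), the proteoglycan SRGN (-1.46 ± 0.11), the cystine transporter SLC7A11 (118 to 33.4, -1.45 ± 0.12) and the lectin receptor CLEC7A (69.9 to 16.5, -1.41 ± 0.12) followed. MT1HL1 (71.9 to 11.6, -1.64), MT1H (60.7 to 12.3, -1.47), PDZRN3 (-1.50) and FCGR2B (-1.45) complete the 10 largest decreases. In signal without the added 16, MT1HL1, MT1H and CLEC7A fell by larger factors than HSP90B1. The metallothioneins and FCGR2B have close paralogs that can share a probe set. All 20 of these genes stayed past the threshold under every alternative run for single genes.

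Of 30 gene lists fixed before the data were examined, 13 moved with Aplidin, and 4 of these held when the correlation between genes was estimated from the data. In the list of endoplasmic reticulum stress genes, 18 of 22 fell and 2 rose (the same counts adjusted over the list alone), with a median log2 fold change of -0.51 (adjusted p = 1.18e-10, and 0.00272 with an estimated correlation). SDF2L1, a cofactor of HSPA5, fell by 1.40 on the log2 scale, from 365 to 128, and the lectin chaperone CALR by 0.91, from 382 to 197. Of 24 genes of the integrated stress response, which tunes amino acid supply, 17 fell and 2 rose (the same adjusted over the list alone; median -0.34, adjusted p = 0.00272 with an estimated correlation). Among them the amino acid transporter SLC7A5 fell from 599 to 244 (-1.24 ± 0.07), and the serine synthesis enzymes PSAT1 and PHGDH by 1.21 and 0.88. Of 19 sterol synthesis genes, 16 fell and 1 rose (the same adjusted over the list alone; median -0.52, adjusted p = 0.00904 with an estimated correlation). They included the sterol sensor INSIG1, from 460 to 165 (-1.40 ± 0.07), MSMO1 (-1.06) and LSS (-0.95). Of 23 NRF2 and oxidative stress genes, 15 fell and 0 rose (16 down and 1 up adjusted over the list alone; median -0.31, adjusted p = 0.00671 with an estimated correlation). Among them were NQO1 (-0.54), TALDO1 (-0.49) and the glutathione synthesis gene GCLM (-0.46).

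**Figure D1:**
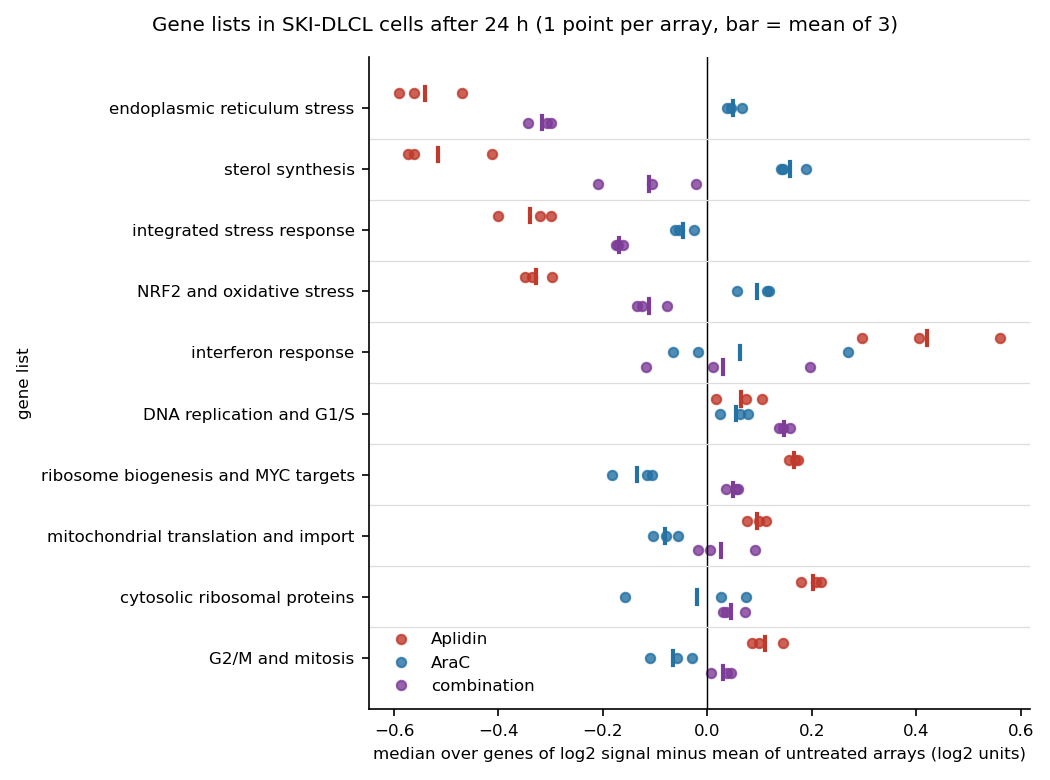
Median log2 signal of 10 gene lists on each treated array of cultured cells, relative to the mean of the 3 untreated arrays, with 1 point per array and a bar at the mean of 3. The endoplasmic reticulum stress list had a median log2 fold change of -0.51 with Aplidin and -0.30 with the combination, and the list of ribosome biogenesis genes -0.13 with AraC; under median scaling the Aplidin medians of the mitochondrial translation list (-0.004), the DNA replication list (-0.067) and the G2/M list (-0.021) turn negative, as do the combination medians of ribosome biogenesis (-0.004), mitochondrial translation (-0.01) and G2/M (-0.019), and several AraC medians.

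The other 9 lists that moved with Aplidin lost their call once the correlation was estimated. Of 29 interferon response genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone; median 0.41, adjusted p = 0.484 with an estimated correlation). MX1, an antiviral GTPase, went from 439 ± 99.2 to 921 ± 212 (1.04 ± 0.24, adjusted p = 0.0032) and SP110 from 261 to 514 (0.93 ± 0.12). Over the 4 cultured groups, 27 of these 29 genes had their highest mean deviation in replicate 1. Of 41 cytosolic ribosomal protein genes, 35 rose and 0 fell (37 and 0 adjusted over the list alone; median 0.20, adjusted p = 0.429 with an estimated correlation). After quantile normalization 7 ribosomal protein genes rose, 2 fell and the list was not called (adjusted p = 0.505). Of 35 ribosome biogenesis and MYC target genes, 19 rose and 3 fell (19 and 4 adjusted over the list alone; adjusted p = 0.187 with an estimated correlation), BYSL by 0.62. Of 28 proteasome genes, 14 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.187 with an estimated correlation), PSMD2 by -0.39. Of 16 NF-kB targets, 8 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), the cytokine LTB by 1.01 ± 0.15 and the adhesion molecule ICAM1 by 0.55. Of 17 immediate early genes, 7 rose and 0 fell (the same adjusted over the list alone; adjusted p = 0.163 with an estimated correlation), KLF10 by 0.62 and DUSP1 by 0.53. Without the filter neither the NF-kB list (adjusted p = 0.0511) nor the immediate early list (0.0568) was called. Of 41 DNA repair genes, 14 rose and 3 fell (15 and 3 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), the checkpoint kinase ATM by 0.65 and CHEK2 by 0.48. The DNA repair list was not called under median scaling (adjusted p = 0.085).

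The study's title asks about mitochondria, and the mitochondrial lists gave mixed values with Aplidin. Of 37 genes of mitochondrial translation and import, 14 rose and 5 fell (16 and 6 adjusted over the list alone; median 0.12 but -0.004 under median scaling, adjusted p = 0.0452, and 0.299 with an estimated correlation). MRPS18B rose from 884 to 1536 (0.78 ± 0.08) and MRPS31 by 0.52. The list was not called under median scaling (adjusted p = 0.276), or without untreated replicate 1 (0.0622), untreated replicate 2 (0.0629) or Aplidin replicate 1 (0.0792). Of 39 oxidative phosphorylation genes, 14 rose and 4 fell (15 and 4 adjusted over the list alone; median 0.09 but -0.03 under median scaling, adjusted p = 0.0483, and 0.525 with an estimated correlation). That call was lost under median scaling (0.699), and without untreated replicate 1 (0.0858), untreated replicate 2 (0.0762), Aplidin replicate 1 (0.0924) or combination replicate 2 (0.0524). NDUFV1 rose by 0.36 and SDHC fell by 0.32. The list of mitochondrial permeability and death factors was not called (1 up and 3 down of 16, adjusted p = 0.511). APAF1, the apoptosome scaffold, fell by 0.52, the pore VDAC1 fell by 0.31 and the caspase activator DIABLO rose by 0.34. Of 23 BCL2 family and caspase genes, 3 rose and 5 fell (adjusted p = 0.146), including the initiator caspase CASP8 (220 to 126, -0.74 ± 0.10) and its inhibitor CFLAR (-0.59 ± 0.12).

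Among single genes picked in advance, MYC rose with Aplidin from 1478 ± 43.7 to 1983 ± 56 (0.42 ± 0.06, adjusted p = 2.74e-05), and DCK, the kinase that activates AraC, from 1323 ± 83.3 to 1687 ± 28.3 (0.35 ± 0.06, adjusted p = 0.000127). VEGFA fell from 207 to 121 (-0.70 ± 0.07), and the cell cycle inhibitor CDKN1A from 72 ± 13.4 to 39 ± 5.3 (-0.67 ± 0.14, adjusted p = 0.00118). EEF1A1, which encodes the protein Aplidin binds, measured 6281 ± 315 with Aplidin beside 5451 ± 210 (0.20 ± 0.07, adjusted p = 0.0231). Its call was lost, and its sign reversed, after quantile normalization (-0.03). The call was also lost without untreated replicate 1 (adjusted p = 0.0886), untreated replicate 2 (0.0568), Aplidin replicate 2 (0.0815) or Aplidin replicate 3 (0.0705). ODC1 rose by 0.20 (adjusted p = 0.00911), but not after quantile normalization or median scaling. The stress factor DDIT3 rose by 0.35 (adjusted p = 0.0152), but not under median scaling, without untreated replicate 1 (0.0513) or without Aplidin replicate 2 (0.0564). BCL2 was at 62 ± 7.9 beside 46.8 ± 1.6 (0.31, adjusted p = 0.0436), and its call was lost under median scaling. Its adjusted p was 0.0786, 0.113 and 0.0853 without untreated replicates 1, 2 and 3, and 0.168 and 0.0579 without Aplidin replicates 2 and 3. It was 0.0502 and 0.0537 without AraC replicates 1 and 2, and 0.0516 without combination replicate 2. None of the other probe sets of VEGFA, BCL2, CNR1, CASP8, APAF1, DUSP1 or MME was called. Not passing were SLC29A1, which carries AraC into cells (0.10), RRM1 (-0.06), RRM2 (-0.05), MCL1 (0.07), BAX (-0.33), GADD45A (0.10), CASP9 (-0.12), CYCS (0.10) and HMOX1 (-0.31). Lists of cell type and cycle were not called either: DNA replication had 15 up and 9 down of 44 (adjusted p = 0.511), with CCNE1 falling by 0.67 and PRIM1 rising by 0.51, and G2/M had 15 up and 5 down of 43 (adjusted p = 0.14). B cell identity had 8 up and 6 down of 30 (adjusted p = 0.589), with MME rising by 0.83 and LMO2 falling by 0.80. The lists of translation factors (17 up and 7 down of 34, adjusted p = 0.054), cytarabine and nucleotide metabolism (7 up and 2 down of 20, 0.069), hypoxia (3 up and 6 down of 28, 0.312), plasma cell genes (3 up and 2 down of 12, 0.795), histones (0 up and 1 down of 11, 0.588) and heat shock (0 up and 1 down of 14, 0.592) did not pass. Adjusted over the list alone, the counts up and down were 15 and 6 for G2/M, 19 and 7 for translation factors, 9 and 2 for the cytarabine list, 4 and 2 for plasma cell genes, 0 and 0 for histones, and unchanged for the other lists not called. Lists for other cell types held few genes above the filter: T and NK cells 4 (none changed), myeloid cells 5 (1 up and 2 down), fibroblasts 6 (1 down, THY1 by -0.64), endothelium 3 (none) and erythroid cells 3 (1 down).

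**Figure D2:**
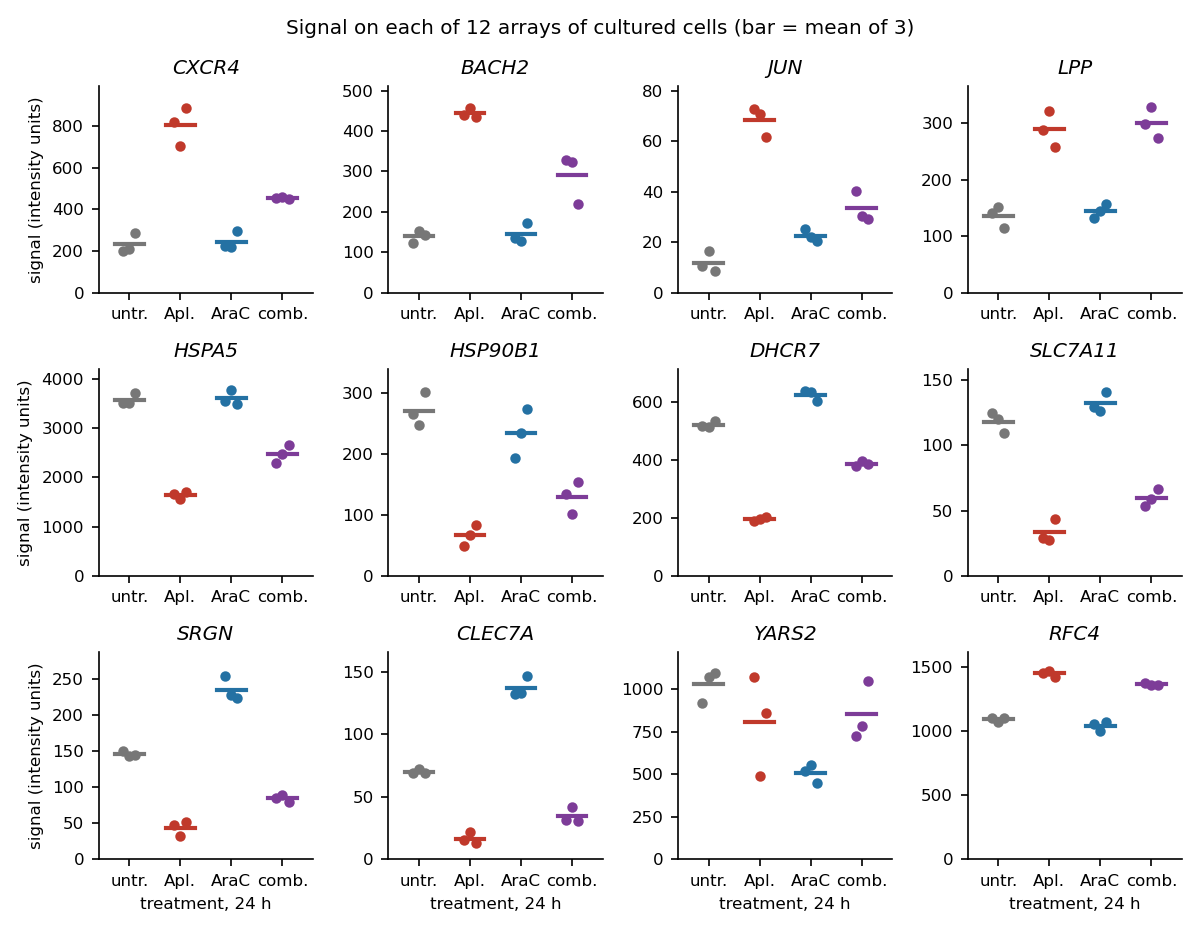
Signal in intensity units of 12 genes on each of the 12 arrays of cultured cells, by treatment, with 1 point per array and a bar at the mean of 3. HSPA5 averaged 3576 untreated, 1639 with Aplidin and 2475 with the combination, while CLEC7A averaged 69.9 untreated, 16.5 with Aplidin and 137 with AraC.

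The second comparison asks what AraC alone changes. Among genes that AraC raised and Aplidin lowered, CLEC7A went from 69.9 ± 2 to 137 ± 8 (mean ± SD, n = 3 each; 0.83 ± 0.12, adjusted p = 0.006) and SRGN from 146 ± 3.4 to 236 ± 16.9 (0.63 ± 0.11, adjusted p = 0.00875). The microtubule protein MAP1A rose from 55.8 to 97 (0.65 ± 0.12), and CCNE2, a cyclin of the G1/S transition, from 350 ± 27.9 to 495 ± 35.3 (0.48 ± 0.07, adjusted p = 0.006). PYROXD1, an oxidoreductase, fell from 159 ± 5.8 to 100.1 ± 9.8 (-0.59 ± 0.09), CCDC69 from 247 to 168 (-0.52 ± 0.08), and POLR3G, a subunit of RNA polymerase III, from 277 to 197 (-0.46 ± 0.07). None of the 20 genes with the largest changes kept its call under every alternative run for single genes. CLEC7A, SRGN, MAP1A, PYROXD1, CCDC69 and POLR3G lost theirs only when 1 replicate number was left out of all 4 groups, as did CCNE2. None of the other probe sets of SRGN, MAP1A, CCNE2, PYROXD1, POLR3G or POLR1C was called.

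AraC changed 290 genes, 167 up and 123 down, none by 1 or more on the log2 scale, and 1460 genes had an unadjusted p under 0.05. Median scaling gave 28 up and 157 down. The treated and untreated values did not overlap for 1973 genes (27.5%, 10% by chance). The count was 54 without untreated replicate 1, 74 without untreated replicate 2, 96 without untreated replicate 3, 67 without AraC replicate 1 and 99 without AraC replicate 2. YARS2, the mitochondrial tyrosyl-tRNA synthetase, had the largest decrease, from 1027 ± 94.3 to 507 ± 53.8 (adjusted p = 0.0136). Its adjusted p was 0.0532 without untreated replicate 2 and 0.0515 without untreated replicate 3. MYC went from 1478 ± 43.7 to 1252 ± 98.8 (-0.24 ± 0.06, adjusted p = 0.0283). For MYC the adjusted p was 0.0771, 0.0784 and 0.099 without untreated replicates 1, 2 and 3, and 0.094 and 0.0693 without AraC replicates 1 and 3. CDKN1A at 108 ± 16.7 beside 72 ± 13.4 (0.50, adjusted p = 0.0514) and JUN at 22.6 ± 2.4 beside 11.8 ± 4.1 (0.48, adjusted p = 0.0578) did not pass, nor did RRM1 (0.14, adjusted p = 0.0806), RRM2 (0.14, 0.119) or DCK (0.02, 0.884).

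The lists of ribosome biogenesis and of mitochondrial translation and import were lower with AraC. Of 35 ribosome biogenesis and MYC target genes, 7 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.13, adjusted p = 3.46e-12, and 0.03 with an estimated correlation). They include the RNA polymerase subunit POLR1C, from 568 to 456 (-0.31 ± 0.05), and MRTO4 (-0.27 ± 0.05). Of 37 genes of mitochondrial translation and import, 6 fell and 0 rose (12 down and 1 up adjusted over the list alone; median -0.08, adjusted p = 1.15e-07, and 0.0412 with an estimated correlation). TIMM13, an import chaperone, fell from 995 to 757 (-0.39 ± 0.06, adjusted p = 0.006). ATF4, the transcription factor of the integrated stress response, fell from 2652 to 2228 (-0.25 ± 0.04). The other 5 lists that moved lost their call with an estimated correlation. These were G2/M with 3 down and 1 up of 43 (5 and 3 adjusted over the list alone; adjusted p = 0.269), translation factors with 4 down of 34 (5 adjusted over the list alone; adjusted p = 0.209), sterol synthesis with 1 up of 19 (6 adjusted over the list alone; adjusted p = 0.209). They were also NRF2 with 0 of 23 (0 adjusted over the list alone; median 0.09 but -0.004 under median scaling; adjusted p = 0.207), and the T and NK cell list with 2 up of 4 tested (2 adjusted over the list alone; adjusted p = 0.269). The NRF2 call, at 0.032, was lost under median scaling (0.256), and without untreated replicate 2 (0.0529), untreated replicate 3 (0.0573) or AraC replicate 2 (0.0977), and the T and NK call, at 0.032, without untreated replicate 3 (0.109) or AraC replicate 1 (0.0864). Without the filter the T and NK list was not called (0.174).

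No other list moved with AraC. Endoplasmic reticulum stress had 0 changed genes of 22 (adjusted p = 0.306), the cytarabine and nucleotide list 0 of 20 (0.22), DNA repair 1 up of 41 (0.437), and DNA replication 1 up of 44 (4 up and 1 down adjusted over the list alone; 0.099). Integrated stress response genes had 2 down of 24 (0.0982), BCL2 family genes 1 up of 23 (4 adjusted over the list alone; 0.4), and interferon genes 1 up of 29 (0.679). B cell identity had 4 up and 1 down of 30 (0.0739), with HLA-DMA rising by 0.31 but not under median scaling. Heat shock had 1 down of 14 (0.0573), NF-kB targets 1 up of 16 (0.0986), immediate early genes 1 down of 17 (0.314), hypoxia 1 up of 28 (0.44), proteasome 1 up of 28 (0.762) and mitochondrial permeability 1 up of 16 (0.869). Ribosomal proteins (0 of 41, 0.0659), histones (0 of 11, 0.158), plasma cell genes (0 of 12, 0.437) and oxidative phosphorylation (0 of 39, 0.553) had none. Adjusted over the list alone, integrated stress response genes had 1 up and 2 down, immediate early genes 1 and 1, and mitochondrial permeability 2 and 0, with the other lists unchanged. Median and test differed in sign for oxidative phosphorylation (median 0.018 but -0.084 under median scaling, direction down) and mitochondrial permeability (median -0.017 but 0.002 after quantile normalization, direction up).

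The third comparison asks what both drugs together did at their lower doses. The combination lowered the endoplasmic reticulum stress list, by less than Aplidin, and raised the DNA replication list. LPP, a protein of focal adhesions, rose from 136 ± 19.6 to 299.7 ± 27.5 (mean ± SD, n = 3 each; 1.06 ± 0.10, adjusted p = 9.44e-06), CLEC2D from 168 ± 8.8 to 367 ± 19.6 (1.06 ± 0.08) and CXCR4 from 233 ± 48 to 454 ± 3.2 (0.93 ± 0.12, adjusted p = 0.000115). USP2, a deubiquitinating enzyme, fell from 99.9 ± 3.2 to 40.5 ± 8.4 (-1.05 ± 0.17, adjusted p = 0.000828), ITGB7 from 587 to 299.2 (-0.94 ± 0.07) and PSAT1 from 667 ± 6 to 373 ± 12.6 (-0.81 ± 0.06, adjusted p = 1.48e-06). In all 1005 genes changed, 552 up and 453 down, and 186 up and 324 down under median scaling. The count was 632 without untreated replicate 1. For 2435 genes (33.9%, 10% by chance) the treated and untreated values did not overlap.

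Other large increases were BACH2 (140 to 291, 0.96 ± 0.13), CD53 (0.93), RUBCNL (0.88), the vesicle GTPase RAB3A (0.84) and JUN (11.8 to 33.4, 0.83 ± 0.14). HSP90B1 (-0.99), SPP1 (-0.94), FCGR2B (-0.91), SDF2L1 (365 to 189, -0.90 ± 0.07), SLC7A11 (-0.82) and the monocarboxylate transporter SLC16A7 (-0.79) fell. Among the 20 genes with the largest changes, 17 kept their call under every alternative run for single genes, and DTNA (0.99), MYL10 (0.94) and MT1H (-1.02) did not. The adjusted p of MYL10, 0.0316, was 0.139 and 0.102 without untreated replicates 2 and 3, and 0.118 and 0.0842 without combination replicates 1 and 2. HMOX1, the oxidative stress enzyme, fell from 45.4 ± 10.6 to 23.1 ± 4.2 (-0.64 ± 0.14, adjusted p = 0.00474). None of the other probe sets of LPP, USP2, JUN, HSP90B1, DTNA, MYL10, PA2G4 or DHCR7 was called. DCK at 1542 ± 65.6 (0.22, adjusted p = 0.014) and MYC at 1682 ± 96.2 (0.18, adjusted p = 0.0401) passed, but not with every array left out in turn. For DCK the adjusted p was 0.0788 without untreated replicate 3 and 0.0675 without combination replicate 2. For MYC it was 0.124, 0.125 and 0.056 without untreated replicates 1, 2 and 3, and 0.164 and 0.0841 without combination replicates 1 and 2. VEGFA (-0.19, adjusted p = 0.0904), RRM1 (0.12, 0.0836), SLC29A1 (0.17, 0.128) and CDKN1A (-0.21, 0.36) did not pass.

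Of 44 DNA replication and G1/S genes, 14 rose and 1 fell with the combination (22 and 2 adjusted over the list alone; median 0.14, adjusted p = 5.5e-06, and 0.00491 with an estimated correlation). Under median scaling 3 rose and 0 fell, with a median of 0.10. RFC4, a clamp loader subunit, went from 1088 ± 18.3 to 1361 ± 13 (0.32 ± 0.04, adjusted p = 0.000131), the helicase subunit MCM7 from 1429 to 1802 (0.33 ± 0.07), and CDC45, another part of that helicase, from 274 to 343 (0.31 ± 0.06, not called under median scaling). Of 22 endoplasmic reticulum stress genes, 14 fell and 1 rose (18 and 1 adjusted over the list alone; median -0.30, adjusted p = 0.00249 with an estimated correlation). HSPA5 went from 3576 to 2475 (-0.53 ± 0.05) and the disulphide isomerase PDIA3 from 1667 to 1124 (-0.56 ± 0.05). Of 24 integrated stress response genes, 10 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 0.00584 with an estimated correlation), with the alanyl-tRNA synthetase AARS1 at -0.47. Of 23 NRF2 genes, 8 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.12, adjusted p = 0.00746 with an estimated correlation), including the ferritin light chain FTL (-0.35) and NQO1 (-0.50).

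A further 6 lists moved with the combination and lost their call with an estimated correlation. Histone genes had 2 down of 11 (5 adjusted over the list alone; median -0.25, adjusted p = 0.0756), and the cytarabine and nucleotide list 4 up of 20 (6 adjusted over the list alone; median 0.11, adjusted p = 0.0756), with the pyrimidine synthesis enzymes CAD (0.39) and CTPS1 (0.37). Under median scaling the nucleotide list was not called (adjusted p = 0.0547). DNA repair had 12 up and 1 down of 41 (15 and 1 adjusted over the list alone; adjusted p = 0.145), and sterol synthesis 6 down of 19 (7 down and 1 up adjusted over the list alone; adjusted p = 0.192), DHCR7 falling by 0.41 and SCD by 0.34. Proteasome genes had 3 down of 28 (2 adjusted over the list alone; adjusted p = 0.192). Ribosome biogenesis had 7 up of 35 (7 up and 1 down adjusted over the list alone; median 0.04 but -0.004 under median scaling; adjusted p = 0.284), with PA2G4 (0.39) and BYSL (0.42), and its adjusted p of 0.033 became 0.159 under median scaling, 0.0522 without untreated replicate 2 and 0.0825 without combination replicate 3. Ribosomal proteins (0 of 41, adjusted p = 0.12), interferon genes (1 up of 29, 0.872), oxidative phosphorylation (1 up and 1 down of 39, 0.897; median 0.02 but -0.021 under median scaling, direction down), mitochondrial translation (6 up and 4 down of 37, 0.826) and B cell identity (6 up and 6 down of 30, 0.843) were not called. Adjusted over the list alone, mitochondrial translation and B cell identity each had 8 up and 7 down, oxidative phosphorylation 0 up and 1 down, and the other 2 lists none.

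Across genes, the combination followed Aplidin. Log2 fold changes of Aplidin and the combination correlated with r = 0.753, where simulated unchanged groups set against the same untreated arrays gave 0.499. Over all genes 77.3% had the same sign, beside 66.7% in the simulations. The covariance was 0.04519, and at most 0.007063 in the simulations. In both, 478 genes rose and 403 fell, with 1 gene opposite. Of the 2667 genes changed by Aplidin, 2512 (94.2%) had the same direction in the combination, 93.6% changed by less, and the median ratio was 0.506. These 3 values have no simulated counterpart here, and choosing genes on the Aplidin change and sharing untreated arrays both move them. The shared set of 881 genes was 569 without untreated replicate 1. For AraC and the combination r was 0.238 (simulated 0.501), while the covariance of 0.007828 lay just above the highest of the simulations (0.007161), and 56.5% of genes had the same sign (simulated 66.7%). The simulated groups hold noise alone, while real changes add spread to the fold changes. Simulated r and same-sign shares are therefore no yardstick for the real ones, and only the covariances can be set side by side. In both, 29 genes rose and 16 fell, and 38 were opposite. For Aplidin and AraC the covariance was 0.001505, beside a simulated mean of 0.006514, and r was 0.03 (simulated 0.499). In both, 30 genes rose and 19 fell, where independent calls would give 31.5 and 22.5, and 111 moved in opposite directions. Genes are not independent replicates, and 3 untreated arrays cannot be split between the comparisons.

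**Figure D3:**
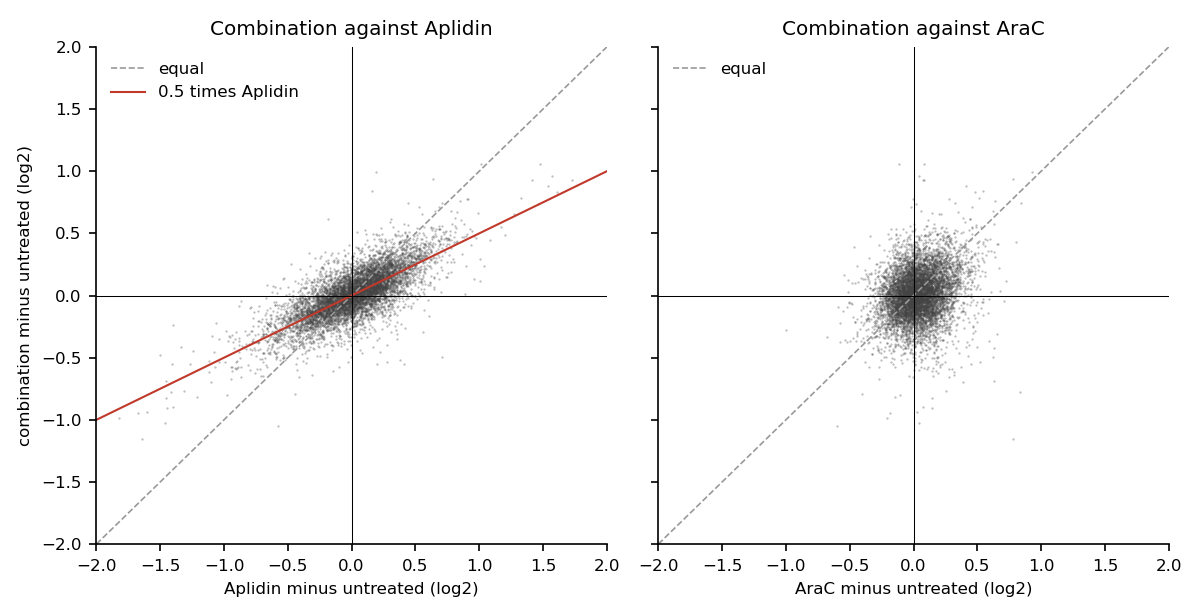
Log2 fold change of each tested gene against untreated cells, with the combination on the vertical axes and Aplidin (left) or AraC (right) on the horizontal axes, 1 point per gene, a dashed line of equal change and a solid line at 0.5 times the Aplidin change. The points follow the Aplidin change (r = 0.753) and lie loosely around that of AraC (r = 0.238).

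Set directly against Aplidin alone, the combination had higher sterol synthesis and endoplasmic reticulum stress genes. INSIG1 rose from 165 ± 18.6 to 388 ± 14.6 (mean ± SD, n = 3 each; 1.17 ± 0.07, adjusted p = 9.83e-08), DHCR7 from 196 to 387 (0.92 ± 0.05), MSMO1 from 430 to 781 (0.84 ± 0.08) and the cytosolic dehydrogenase IDH1 from 122 to 234 (0.86 ± 0.10). The calcium channel subunit CACNG4 fell from 95.2 ± 32.9 to 31.1 ± 5 (-1.21 ± 0.24, adjusted p = 0.00388), LTB from 302 to 155 (-0.89 ± 0.15) and JUN from 68.4 to 33.4 (-0.78 ± 0.14). In all 983 genes differed, 557 up and 426 down, and 616 up and 104 down under median scaling. The count was 534 without combination replicate 3 and 652 without combination replicate 2. The 2 groups did not overlap for 2164 genes (30.1%, 10% by chance).

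Sterol synthesis had 14 of 19 genes up and 0 down against Aplidin (15 and 0 adjusted over the list alone; median 0.42, adjusted p = 0.00368 with an estimated correlation). Integrated stress response genes had 13 up and 1 down of 24 (15 and 1 adjusted over the list alone; adjusted p = 0.00368 with an estimated correlation), SLC7A5 by 0.79. Endoplasmic reticulum stress had 10 up of 22 (12 adjusted over the list alone; adjusted p = 0.00573 with an estimated correlation), CALR by 0.61 and HSPA5 by 0.59. NRF2 had 9 up of 23 (11 up and 2 down adjusted over the list alone; adjusted p = 0.0302 with an estimated correlation), and DNA replication 11 up and 2 down of 44 (14 and 2 adjusted over the list alone; adjusted p = 0.0197 with an estimated correlation), with CCNE1 (0.53), ORC1 (0.47) and CCNE2 (0.46). VEGFA was higher than with Aplidin alone (121 to 179.7, 0.51 ± 0.07). None of the other probe sets of VEGFA, JUN, CACNG4 or CCNE2 was called. Interferon genes had 9 down of 29 (14 adjusted over the list alone; median -0.45) and ribosomal proteins 15 down of 41 (29 adjusted over the list alone; median -0.15), both with an adjusted p of 0.284 with an estimated correlation. The ribosomal protein call was also lost after quantile normalization (adjusted p = 0.255). Calls were likewise lost for NF-kB targets (5 down of 16, adjusted p = 0.232 with an estimated correlation), translation factors (2 up and 8 down of 34, 0.284) and immediate early genes (3 down of 17, 0.0889). They were also lost for oxidative phosphorylation (4 down of 39, 0.284), mitochondrial translation (9 down of 37, 0.116) and ribosome biogenesis (1 up and 5 down of 35, 0.263), whose medians turn positive under median scaling (0.016, 0.002 and 0.012). Median scaling also ended the calls of translation factors (adjusted p = 0.134), oxidative phosphorylation (0.126) and ribosome biogenesis (0.156). Adjusted over the list alone, the counts up and down were 0 and 5 for NF-kB targets and for immediate early genes, 3 and 14 for translation factors, 0 and 4 for oxidative phosphorylation, 3 and 11 for mitochondrial translation and 2 and 10 for ribosome biogenesis. The immediate early call was also lost without combination replicate 2 (0.0595). Heat shock had 2 up of 14 (3 adjusted over the list alone) and the proteasome 5 up of 28 (5 adjusted over the list alone), both at 0.338 with an estimated correlation. Heat shock was not called without Aplidin replicate 3 (0.0516), or combination replicates 1 or 3 (0.0524 each). The proteasome list was not called without untreated replicates 1, 2 or 3 (0.0535, 0.0555 and 0.0532), Aplidin replicate 3 (0.199), AraC replicate 1 (0.0549), or combination replicates 1 or 3 (0.121 and 0.0514).

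Against AraC alone, the combination had lower endoplasmic reticulum stress genes and higher ribosome biogenesis genes. CLEC7A fell from 137 ± 8 to 34.3 ± 6.2 (mean ± SD, n = 3 each; -1.61 ± 0.12, adjusted p = 4.68e-07), SRGN from 236 to 84.8 (-1.32 ± 0.11), the lysozyme gene LYZ from 87.8 to 31.6 (-1.12 ± 0.17), LY96, a coreceptor for lipopolysaccharide, from 546 to 249.8 (-1.08 ± 0.06), as did MT1HL1 (-1.94). CLEC2D rose by 1.17, LPP by 0.98, BACH2 by 0.92, CXCR4 by 0.86 and CD53 by 0.85. MYC was higher (1252 to 1682, 0.42 ± 0.06, adjusted p = 6.72e-05), and HMOX1 (-0.96 ± 0.14) and CDKN1A (108 to 60.1, -0.71 ± 0.14) were lower. In all 1574 genes differed, 726 up and 848 down, and 688 up and 381 down under median scaling, and 2611 genes (36.4%, 10% by chance) did not overlap. Of 15 list calls 3 held with an estimated correlation. They were those of endoplasmic reticulum stress with 17 of 22 down (18 down and 1 up adjusted over the list alone; median -0.40, adjusted p = 0.00405), NRF2 with 15 of 23 down (17 adjusted over the list alone; adjusted p = 0.00545) and ribosome biogenesis with 18 of 35 up (20 adjusted over the list alone; median 0.22, adjusted p = 0.0155), among them NOP2 (0.51) and PA2G4 (0.49). Sterol synthesis (9 of 19 down, 12 adjusted over the list alone), the integrated stress response (9 of 24 down and 2 up, the same adjusted over the list alone), mitochondrial translation (11 of 37 up and 1 down, 14 and 1 adjusted over the list alone) and DNA replication (9 of 44 up and 3 down, 13 and 3 adjusted over the list alone) each had an adjusted p of 0.0591 with an estimated correlation. DNA replication also lost its call after quantile normalization (adjusted p = 0.0907). The other probe sets of LPP were not called.

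The remaining 8 list calls against AraC were also lost with an estimated correlation. DNA repair had 11 up and 1 down of 41 (15 and 1 adjusted over the list alone; adjusted p = 0.105), translation factors 10 up and 2 down of 34 (11 and 2; 0.205), and G2/M 12 up and 2 down of 43 (12 and 2; 0.296). The proteasome had 5 down of 28 (7 adjusted over the list alone; 0.205), and no call under median scaling (0.164). Heat shock had 6 up and 2 down of 14 (the same adjusted over the list alone; 0.292), and no call after quantile normalization (0.0759) or without AraC replicate 3 (0.13). Ribosomal proteins had 1 up of 41 (0 adjusted over the list alone; 0.604), and no call after quantile normalization (0.597) or without AraC replicate 3 (0.633). Of 5 myeloid genes 2 were lower (2 adjusted over the list alone; adjusted p = 0.0458, and 0.178 with an estimated correlation). That list was not called without the filter (0.553), or without AraC replicates 1 or 2 (0.0517 and 0.0838) or combination replicates 1 or 2 (0.0658 and 0.0632). Immediate early genes had 4 up of 17 (4 adjusted over the list alone; adjusted p = 0.0482, and 0.13 with an estimated correlation). They were not called under median scaling (0.0669), or without untreated replicate 1 (0.0501), Aplidin replicate 1 (0.0543), AraC replicates 1 or 2 (0.0501 and 0.0739), or combination replicates 1 or 3 (0.139 and 0.0571).

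The single drugs differed most from each other. MLLT11, a fusion partner of KMT2A in leukaemia, was at 413 ± 45.2 with Aplidin and 1388 ± 79.7 with AraC (mean ± SD, n = 3 each; -1.72 ± 0.07, adjusted p = 1.06e-10), CLEC7A at 16.5 and 137 (-2.25 ± 0.12), SRGN at 43.8 and 236 (-2.09 ± 0.11), PDZRN3 at 34.2 and 147 (-1.72) and MT1HL1 at 11.6 and 131 (-2.42). CXCR4 was higher with Aplidin by 1.66, CLEC2D by 1.59, BACH2 by 1.53, CNR1 by 1.44 (its other probe sets not called) and the interferon gene IFI44L by 1.34. MYC was at 1983 ± 56 with Aplidin and 1252 ± 98.8 with AraC (0.66 ± 0.06, adjusted p = 1.58e-07), and CDKN1A at 39 ± 5.3 and 108 ± 16.7 (-1.17 ± 0.14). In all 3008 genes differed, 1393 up and 1615 down, and 3486 (48.6%, 10% by chance) did not overlap. With an estimated correlation 6 of 14 list calls held. They were those of sterol synthesis (16 of 19 down, also adjusted over the list alone; adjusted p = 0.00929), endoplasmic reticulum stress (18 of 22 down and 1 up, also adjusted over the list alone; adjusted p = 0.00633), NRF2 (16 of 23 down, also adjusted over the list alone; adjusted p = 0.00671). They were also those of the integrated stress response (13 of 24 down and 1 up, 14 and 1 adjusted over the list alone; adjusted p = 0.00929), ribosome biogenesis (24 of 35 up and 1 down, also adjusted over the list alone; adjusted p = 0.0244) and mitochondrial translation (18 of 37 up and 2 down, 19 and 2 adjusted over the list alone; adjusted p = 0.0498). Of 41 ribosomal protein genes 37 were higher with Aplidin and 0 lower (37 and 0 adjusted over the list alone), with an adjusted p of 0.352 with an estimated correlation and 0.276 after quantile normalization. Calls were likewise lost with an estimated correlation for translation factors (21 up and 6 down of 34, the same adjusted over the list alone; 0.203), DNA repair (16 up and 4 down of 41, the same; 0.203) and the proteasome (1 up and 14 down of 28, the same; 0.203). They were lost too for G2/M (19 up and 3 down of 43, 20 and 4 adjusted over the list alone; 0.351), interferon genes (13 up and 1 down of 29, 14 and 1; 0.448), immediate early genes (9 up of 17, 9; 0.0631) and oxidative phosphorylation (14 up and 3 down of 39, 15 and 4; 0.416). The last was also not called after quantile normalization (0.637), under median scaling (0.0866), or without Aplidin replicate 1 (0.0549) or AraC replicate 3 (0.125). CYCS, the cytochrome c gene, was at 4660 ± 99.7 with Aplidin and 4273 ± 234 with AraC (0.13, adjusted p = 0.0379), with the sign reversed by quantile normalization (-0.081). Its adjusted p was 0.0504 without untreated replicate 2, 0.0978 and 0.0881 without Aplidin replicates 2 and 3, and 0.0547 and 0.136 without AraC replicates 1 and 3.

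The last comparison describes the treated tumour beside the untreated one, with 1 array each and no test. B cell genes were lower and T cell genes higher in the treated tumour. MS4A1, the CD20 antigen, had a signal of 1128 in the untreated tumour and 243 in the treated one, PAX5 470 and 118, BCL6 1007 and 290, and CD79B 969 and 398. CD3D, a chain of the T cell receptor complex, had 1525 and 4521, CD8A 54.8 and 722 (log2 difference 3.38) and the granzyme GZMA 110 and 523. Of 30 B cell identity genes 29 were lower (median -1.13, lower than all of 10000 random lists of matched expression), and of 17 T and NK cell genes 16 were higher (median 0.82, percentile 100). Of the T and NK genes, 4 were among the genes tested in culture, LCK having a signal of 529 there.

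Other large differences in the treated tumour were higher SOSTDC1 (2.96), SRGN (2.94), CD69, an activation marker of lymphocytes (2.78), TFPI (2.54), APOBEC3B (2.48), CDKN2D (2.48), the stress transcription factor ATF3 (53.9 and 361, 2.43), LGALS1 (2.40) and S100P (2.33). Lower genes were RUBCNL (559 and 36, -3.47), IFI44L (382 and 21.9, -3.39), SPP1 (2176 and 243, -3.08), IFI27 (-3.01), the receptor kinase MET (-2.90), RASGRP3 (-2.76), PPP1R10 (-2.73), MX1 (1389 and 199, -2.71), OAS1 (-2.67) and DEPTOR (-2.65). The difference was 1 or more on the log2 scale for 787 genes, 285 higher and 502 lower, and 376 with a pseudocount of 64. Of 32 interferon response genes 26 were lower (median -0.98, percentile 0), of 16 heat shock genes 13 (median -0.73, percentile 0; HSPH1 1153 and 196), and of 35 ribosome biogenesis genes 30 (median -0.67, percentile 0). Only 6 of the interferon genes lay within 2-fold of untreated culture, and their median was -0.58. Of 18 immediate early genes 15 were higher (median 0.68 but 0.352 for all 30 without the filter, percentile 100; JUN 227 and 503), although MYC had 1503 and 425, and of 43 G2/M genes 36 were higher (median 0.31, percentile 99.9).

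Other lists lay less far out, although several, such as mitochondrial translation, the proteasome and myeloid genes, were still near the ends of the random lists. Mitochondrial translation was at the percentile 1.54 (median -0.28), the proteasome at 2.13, translation factors at 3.56, DNA repair at 5.39 and sterol synthesis at 7.94. Ribosomal proteins were all higher (41 of 41, median 0.31 but 0.016 after quantile normalization, percentile 95.98) and histones 9 of 11 (percentile 96.52). Endoplasmic reticulum stress was at 93.35, BCL2 family genes at 70.49, DNA replication at 70.63, NF-kB targets at 63.3, the integrated stress response at 41.62, hypoxia at 31.23, oxidative phosphorylation at 28.5, the cytarabine list at 25.56, NRF2 at 24.11, mitochondrial permeability at 15.43 and plasma cell genes at 11.19. For NF-kB targets the median was 0.018, but -0.369 for all 24 genes without the filter and -0.612 for the 9 within 2-fold of untreated culture. Of the lists for other cells, 5 myeloid genes had a median of 0.73 (percentile 99.64), 9 fibroblast genes -0.08 but 0.008 after quantile normalization (36.74), 5 endothelial genes -0.23 (18.01) and 2 erythroid genes -0.38 (11.54). Without the filter the medians were 0.323 for 23 myeloid genes, and positive for 25 fibroblast (0.111), 17 endothelial (0.046) and 10 erythroid genes (0.039).

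**Figure D4:**
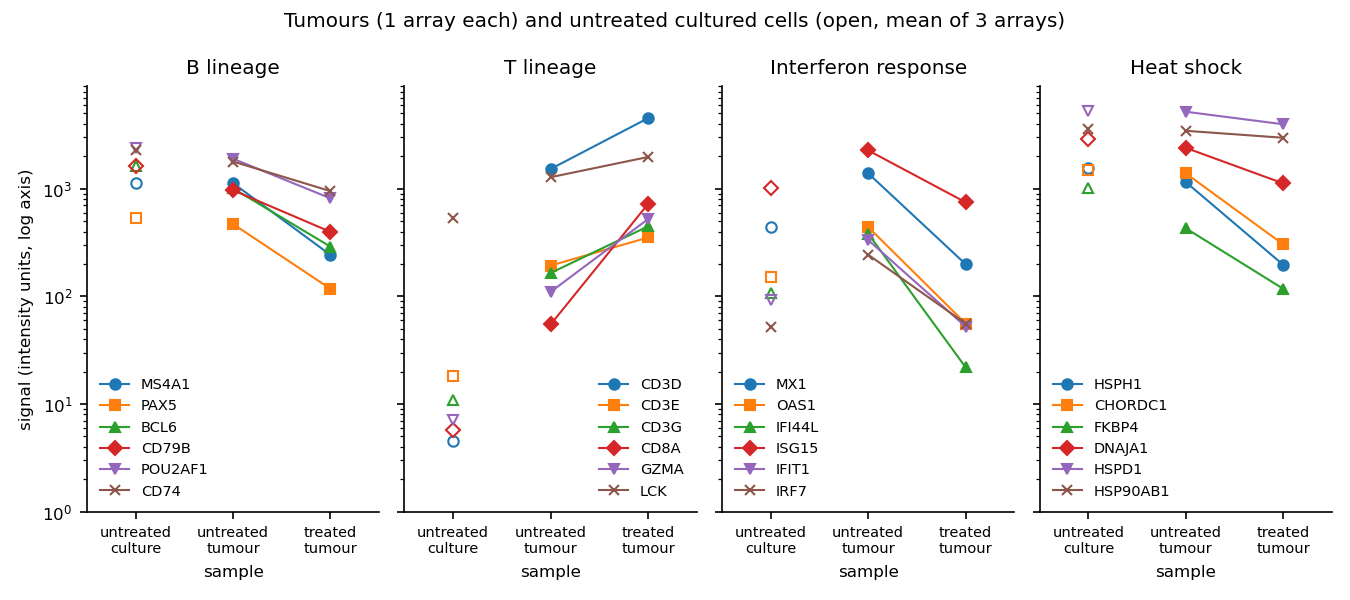
Signal on a log axis, in intensity units, of 6 genes in each of 4 lists in untreated cultured cells (left, open symbols or a cross, mean of 3 arrays), the untreated tumour and the treated tumour (1 array each, joined by lines). CD3D goes from 4.5 in culture to 1525 and 4521 in the tumours, and MS4A1 from 1141 in culture to 1128 and 243.

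Changes in the tumour did not follow those of the combination in culture. Over 6537 genes the tumour difference and the combination's log2 fold change in culture correlated with r = -0.027 and rho = 0.001 across genes, which are not independent replicates. Of 969 genes changed by the combination in culture, 450 (46.4%, exact 95% interval 43.3 to 49.6) had the same sign in the tumour, 185 of 527 genes that rose and 265 of 442 that fell. The interval treats genes as independent and does not cover variation between tumours, with 1 array each. It therefore does not show a response opposite to that in culture. The tumours also differed in B and T cell genes, and the treated tumour was sampled on day 8 but the cultures at 24 h. A drug response in the tumour cannot be told apart from a difference in cell content here. For Aplidin the share was 50.2% (1279 of 2548 genes, r = -0.03), and for AraC it was 62.8% (177 of 282 genes, r = 0.134). The untreated tumour itself differed from untreated culture: 81 genes were higher in it by 3 or more on the log2 scale and 4 lower. ITM2A, a membrane protein of developing T cells, had a signal of 3.1 in culture, 3830 in the untreated tumour and 5712 in the treated one, and the embryonic globin HBE1 7.4, 3930 and 851. The same values were, for the intermediate filament VIM, 12.3, 2161 and 4252, and for the recombinase RAG1, 5.7, 723 and 112. ITGB7 was lower in the untreated tumour (51.5 beside 587 in culture). The untreated tumour correlated with untreated culture at r = 0.942 across genes and the treated one at r = 0.886.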

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

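All tests below on the tumours and on interferon genes, the test of lists against 0.5 times the Aplidin change, and the dose-weighted values of sterol synthesis and histones were chosen after the result was seen; the shared-array test, the gene count against 0.5 times the Aplidin change, the dose-weighted test of DNA replication and the splits were written before.

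The treated tumour had lower B cell genes and higher T cell genes, with CD3D at 1525 in the untreated tumour and 4521 in the treated one, and MS4A1 at 1128 and 243. A second human cell population with a larger share in the treated tumour could give this pattern. Of 116 genes almost absent from culture and present in the untreated tumour, 108 lay outside the T and NK list. Their median difference was 0.56 (percentile 100 of random lists). These genes were picked on the same tumour array and still include T-lineage genes such as TRBC1 (711 and 1215). Their rise restates part of the pattern and is no separate support for a second population. The T and NK list itself was at the percentile 100, its most abundant genes were CD3D and LCK (1279 and 1972), and the cultured line also expresses 4 of its genes above the filter. A change of share alone was left undecided, as 6% of the 116 genes were lower by 1 or more. The control transcripts gave no sign of RNA degradation in 1 tumour. The ratio between the GAPDH 3 prime to 5 prime ratios of the tumours was 1.014, and the ACTB ratios were 1.279 untreated and 1.31 treated. Such control transcripts cannot exclude degradation of other RNAs.

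Over the cultured groups, 27 of 29 interferon genes had their highest mean deviation in replicate 1. Chance order gave an exact permutation p of 0.00463, the smallest that the arrangements allow, and 0.139 after adjustment over the lists. A list that alone reaches the smallest p cannot go lower after this adjustment. The adjusted value therefore cannot decide whether the order was chance. A batch over all genes was excluded (mean correlation of same-numbered arrays without these genes, -0.002). The GAPDH ratio did not follow the replicate number, with replicate 1 at the same end in 1 of 4 groups. A single control transcript cannot exclude RNA quality as a source.

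Combination changes followed those of Aplidin, with a median ratio of 0.506 among genes chosen on the Aplidin change. The untreated arrays that both comparisons share were excluded as the source, with a covariance of 0.04519 beside at most 0.007063 in simulations. Aplidin at its lower dose, acting in proportion, could account for genes at large, as 64 of all 7178 genes (0.89%) departed from 0.5 times the Aplidin change. That share includes the many genes that the combination did not change. Small departures can also be missed, as 25.4% of simulated changes of 0.25 were recovered for the combination. On the log2 scale this account was excluded for 3 of 30 lists, DNA replication, sterol synthesis and histones (adjusted p = 0.000901, 0.0185 and 0.0299). In these lists 3 of 44, 5 of 19 and 1 of 11 genes departed singly. For DNA replication, single-drug effects that add up in proportion to dose on the log2 scale were excluded as well (adjusted p = 0.00119 with an estimated correlation). The same held for sterol synthesis (0.0351) but not for histones (0.0556). Effects in proportion to dose in signal, without the log2, were not tested, and a response that is not linear in dose stays open.

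The count of genes changed by any treatment was reached by 1 of 100 random splits, the real one, and the highest other split gave 138, so chance is excluded. For each of the 6 comparisons of 2 groups the splits are too few to tell, the real split being 1 of 10. The real counts were 2667, 290, 1005, 983, 1574 and 3008, and the highest other split gave 0, 0, 1, 1, 0 and 0.

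Ribosome biogenesis genes had a median of -0.668 in the treated tumour and 0.04 (-0.004 under median scaling) with the combination in culture, and the difference was not tested.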

How the results depend on the processing

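Leaving a replicate number out of all groups, and leaving out single arrays for lists and the shared response, were chosen after seeing the data; in every case below the cause was not tested.

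The Aplidin count of 2667 was 4135 with all probe sets, 1755 without replicate 2 in all groups, and 2164 to 2706 with 1 array left out. The AraC count of 290 was 132 without a filter, 185 under median scaling, 116 without a trend, 3, 12 and 122 without replicates 1, 2 and 3 in all groups, and 54 to 386 with 1 array left out. The combination count of 1005 was 510 under median scaling, 416, 413 and 493 without replicates 1, 2 and 3 in all groups, and 632 to 1100 with 1 array left out.

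Against Aplidin, the combination count of 983 was 463, 357 and 508 without replicates 1, 2 and 3 in all groups, and 534 to 1098 with 1 array left out. Against AraC, 1574 became 831 and 874 without replicates 1 and 2 in all groups, and 1204 to 1676 with 1 array left out. The single drugs, at 3008, gave 4702 with all probe sets and 2595 to 3022 with 1 array left out. Any treatment, at 3053, gave 4694 with all probe sets, 1944 without replicate 2 in all groups, and 2707 to 3025 with 1 array left out. The shared 881 genes became 448 under median scaling, 364, 371 and 447 without replicates 1, 2 and 3 in all groups, and 569 to 899 with 1 array left out.

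List calls numbered 74, and 24 with an estimated correlation, 113 with fry and 69 to 79 with 1 array left out. The tumour count of 787 was 376 with a pseudocount of 64. With the replicate number as a replicate block the counts were 2609 for Aplidin, 268 for AraC and 914 for the combination. Over all genes the numbers do not pair arrays, as 18 pairs of same-numbered arrays had a mean correlation of 0.005, although over the interferon genes it was 0.268.

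Among tested calls, a direction reversed in 4 results. Ribosomal proteins, combination against AraC, lost their call and turned without replicate 3 in all groups (adjusted p = 0.907), and also lost it with an estimated correlation (0.604) and with fry (0.279). CYCS, Aplidin against AraC, reversed under quantile normalization (-0.081, adjusted p = 0.0566), as did EEF1A1 against AraC (adjusted p = 0.388) and against untreated (adjusted p = 0.433).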

Other observations

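The hypotheses below were formed after the results were seen, and their tests were chosen then, except the gene count against 0.5 times the Aplidin change and the dose-weighted test of DNA replication.

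With Aplidin alone, the lists of endoplasmic reticulum stress, sterol synthesis and the integrated stress response were lower together, with 18 of 22, 16 of 19 and 17 of 24 genes down. The 2 drugs shared no more calls than independent ones would: 30 genes rose and 19 fell with both, where 31.5 and 22.5 would be expected. Another 111 genes moved in opposite directions. The covariance of their changes (0.001505) lay below the simulated mean for unchanged groups with the same untreated arrays (0.006514). Across genes their changes thus leaned in opposite directions, although genes are not independent replicates.

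A dose of 1.5 nM Aplidin may explain many of the combination changes, but the gene count cannot show it. Of all genes tested, 0.89% departed from 0.5 times the Aplidin change. That share includes the many genes unchanged by the combination, and small departures can be missed. On the log2 scale the DNA replication and sterol synthesis lists departed (adjusted p = 0.00119 and 0.0351 beside dose-weighted single drugs). These departures may reflect a response not linear in dose on that scale or an effect of both drugs. Arrays of Aplidin at 1.5 nM and of AraC at 5 nM alone would separate these.

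A second human population might be present in both tumours, as 116 genes almost absent from culture were present in the untreated tumour. The percentile 100 of those outside the T and NK list describes a difference between the tumours, and does not bear on presence in both. ITM2A, TRBC1 and RAG1 measured 3830, 711 and 723 in the untreated tumour and 3.1, 8.5 and 5.7 in culture. In the treated tumour they measured 5712, 1215 and 112, so RAG1 was lower there while the other genes were higher. Other sources of these signals were not tested. Genotyping of tumour and line, with staining for CD3 and CD20, would test it.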
